A study of Sus scrofa with 8 samples.

How the data were processed

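Messenger RNA of pig (Sus scrofa) cells was sequenced at 4 stages of differentiation, with 2 libraries per stage: pluripotent stem cells (PSC), definitive endoderm (DE), anterior foregut endoderm (AFE) and lung progenitor organoids (LPO). The column headers name PSC and LPO by other words, EPSC and Organoid, and were matched to the stages through the sample labels. Per the labels, RNA was extracted with Trizol, captured with oligo(dT) beads, made into stranded libraries and sequenced as pairs on an Illumina NovaSeq. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, without versions for the last pair and without saying what each tool made. The genome build is not given in the sources used here.

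A single table of 25578 genes with Ensembl pig identifiers was deposited, with a column per library and none pooled. It holds the authors' expected counts (estimated counts per gene) and FPKM computed by the authors (fragments scaled by transcript length and library size). The deposited expected counts are whole numbers, so no rounding was needed, and carry no scaling between libraries. Of the values from 1 to 12, 46.4% to 50.7% per library lay at 4, 8 or 12, so about 4 counts stand for 1 read pair, and the total counts of 36004372 to 67566269 per library correspond to about 9001093 to 16891567 read pairs. Genes above 0 numbered 16810 to 20724 per library. The floor of 3 read pairs (12 counts) per library lies at 0.150 to 0.357 counts per 1e6 counts (CPM). FPKM sums were 345563 and 347824 in LPO and 439098 to 467008 in the other stages. Between the libraries of a stage, the median variance in read pairs was 4.64 (PSC), 5.75 (DE), 2.38 (AFE) and 2.07 (LPO) times the Poisson variance, and 83.3%, 85.4%, 86.8% and 91.3% of genes lay within 2-fold.

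Gene symbols came from the deposited table, with 130 filled in from a reference table of gene names, and 10013 genes had none. The 31 gene lists hold 594 members, of which 550 are in the file, and the panel of 30 core genes is there in full. Members without an entry, such as the proliferation antigen MKI67 and alpha-fetoprotein (AFP), were not analysed here.

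Calculations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures Python 3.11.15 with matplotlib 3.10.9. Counts of 19346 genes that passed filterByExpr were scaled with TMM (factors 0.901 to 1.27). A quasi-likelihood model with the 4 stages as groups was fitted to all 8 libraries (glmQLFit, 4 residual degrees of freedom). The steps DE against PSC, AFE against DE and LPO against AFE, the net comparison LPO against PSC, and an F test among the stages were tested with glmQLFTest. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and changes of 2-fold or more were counted besides. The stage of highest mean was read from log2 CPM with a prior count of 2, and principal components from the 500 most variable genes on the same scale.

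Gene lists were tested with camera (preset correlation 0.01, and with an estimated correlation) and with fry, adjusted over the 31 lists of a comparison. Camera compares a list with all other genes, whereas fry asks whether its genes move at all. Fry called 27, 25, 26 and 30 lists in DE against PSC, AFE against DE, LPO against AFE and LPO against PSC, and in either direction 31 in each. Camera called 12, 12, 7 and 16 lists, all in the direction fry gave, and with an estimated correlation 0, 3, 1 and 1. KEGG pathways of 10 to 300 tested genes (318), taken from the deposited table's own column, were tested with camera as well, a test added after the files were seen. Correlated genes are the reason for both correlations: with few residual degrees of freedom the estimated correlation is imprecise, and the preset one may be too low.

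The comparisons, lists, core panel, alternatives and naming rule were fixed before the data were examined. Named genes are, per comparison, the 5 largest rises and 5 largest falls among called genes that carry a symbol, reach 5 FPKM in the higher stage and do not overlap between stages, the core panel, up to 4 called members of each list with the smallest adjusted p, and the 5 genes per stage with the widest gap to the next stage. Members that ran against their list are named besides, picked after their values were seen. Some genes that the rule names are not reported here. Where several entries share a symbol, that with the highest mean is used. Of 154 genes named in the comparisons, 14 overlap another gene in the file, and in 6 of them that gene holds 10% or more of their count. These are CDK1, HABP2, MCM2, MCM7, NODAL and PAX9, each with its neighbour on the opposite strand, and their values are uncertain to that extent.

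Alternatives were no filter and a filter of 5 FPKM in 2 libraries, DESeq2 size factors, median centring, no mean-variance trend, the DESeq2 Wald test, limma on log2 FPKM with pseudocounts of 1, 0.5 and 0.1, the replicate number as a block, only the 4 libraries compared, and leaving out each library. Quantile-normalized FPKM and counts divided by 4 were added after the data were seen. Gene lists were run with an estimated correlation, DESeq2 size factors, median centring, quantile-normalized FPKM, counts divided by 4, the block and each library left out. They were not run with the filters, without the trend, with the DESeq2 Wald test, with limma on other FPKM or with only the 4 libraries. Flags for single unusual samples and counts of other splits of the samples need larger groups than 2 libraries and were not made.

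The workflow was tested on simulated data with known changes in 200 genes, present in DE against PSC and in AFE against DE. The changed genes were drawn from those with a mean of 20 read pairs or more per library. Every simulated gene took its spread from the fitted trend. Recovery near the floor, or for genes with a spread off the trend, was therefore not tested. In the real data 35.3% (AFE against DE) to 70.3% (LPO against PSC) of tested genes were called. The simulation therefore does not show recovery or false calls, or how scaling behaves, when so large a share of genes changes. With edgeR on 18511 simulated genes, 73% of 2-fold and 92% of 4-fold changes were recovered in DE against PSC (73% and 95% in AFE against DE), with 8 and 5 unchanged genes called. DESeq2 on the same genes recovered 74% and 93% (74% and 96%), with 35 and 23 unchanged genes called. Limma on 13960 genes recovered 64% and 81% (61% and 84%), with 11 and 10 unchanged genes called, and edgeR on read pairs (16034 genes) 74% and 91% (74% and 95%), with 10 and 4. In LPO against AFE and LPO against PSC, where nothing was changed, edgeR called 0 with counts or read pairs, DESeq2 5 and 0, and limma 0 genes. A list made only of genes raised 2-fold was found (camera adjusted p = 1.1e-64) and 0 of 20 random lists were called. Because the simulated genes were independent, this does not show how list calls behave when genes are correlated.

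Lists of fibroblast, smooth muscle and primitive endoderm genes were added to weigh patterns seen in the results, and their outcome is given with the other observations.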

Results

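Pig pluripotent stem cells (PSC) were differentiated through definitive endoderm (DE, the germ layer that lines the gut and its organs) and anterior foregut endoderm (AFE, the front of the gut tube, from which the lung buds) to lung progenitor organoids (LPO). Each of the 4 stages had 2 libraries of messenger RNA. Deposited counts per library summed to 36004372 and 42251431 in PSC and to 61748702 to 67566269 in the other stages. Low counts gathered at 4, 8 and 12, so that about 4 counts stood for 1 read pair. The depth thus came to about 9001093 to 16891567 read pairs per library. The 100 most abundant genes held 22.8% and 22.9% of the counts in LPO, against 29.1% to 33.7% in the other stages. EEF1A1, a translation elongation factor, was the most abundant gene in PSC, AFE and LPO, and the simple-epithelial keratin KRT8 in DE.

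Levels are given as counts per 1e6 counts after TMM scaling (CPM), as mean ± SD with n = 2. Every adjusted p for a gene is a Benjamini-Hochberg value of the edgeR quasi-likelihood test over 19346 genes. A gene at 0 in both libraries of a stage has its fold given as a bound, computed against a floor of 3 read pairs (12 counts) in each library, 0.150 to 0.357 CPM. With 1 to 3 read pairs over a stage, the ratio is given with a 95% counting interval. Bound and interval cover counting error only. Nothing in the labels says that the 2 libraries of a stage came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333. Gene lists were fixed before the data were examined, and members named without values were picked after their values were seen.

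The stages lay in the order of the protocol along the main axis of variation. Principal component 1 of the 500 most variable genes held 63.9% of the variance, with PSC at −91.5 and −92.5, DE at −16.6 and −23.7, AFE at 32.0 and 30.9, and LPO at 80.8 and 80.5. Component 2 held 21.0% and component 3 held 11.5%. Across genes, which are not independent replicates, Pearson r of log2 CPM was 0.962 (PSC), 0.972 (DE), 0.974 (AFE) and 0.982 (LPO) within a stage and 0.735 to 0.911 between stages. Of 19346 genes, 15323 differed among the 4 stages (edgeR quasi-likelihood F test, adjusted p under 0.05). Of these, 4080 were highest in PSC, 2559 in DE, 2706 in AFE and 5978 in LPO.

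The genes with the widest gap between their peak stage and the next stage marked each stage. In PSC they were PRDM14 (a repressor that guards pluripotency, 65.6 CPM), LEFTY2 (an inhibitor of NODAL signalling, 2577 CPM), VSNL1 (a neuronal calcium sensor, 56.6 CPM), CBLN1 (a secreted synapse organiser, 68.2 CPM) and a gene without a symbol (106 CPM). In DE they were the natriuretic peptides NPPA (61.8 CPM) and NPPB (17.4 CPM), the apolipoprotein APOC3 (15.2 CPM), the citrate transporter SLC13A5 (32.4 CPM) and a gene without a symbol (523 CPM). In AFE they were the protease inhibitor SERPINA1 (14.9 CPM), the secreted phospholipase PLA2G2E (18.4 CPM), the hyaluronan-binding ITIH2 (23.4 CPM), the glucosidase GBA3 (7.69 CPM) and a gene without a symbol (7.49 CPM). In LPO they were TNMD (tenomodulin, a tendon membrane protein, 10.3 CPM), CLCA1 (secreted by goblet cells, 9.72 CPM), TCN1 (a cobalamin carrier, 9.49 CPM), MMP12 (a macrophage elastase, 9.33 CPM) and the tyrosine kinase FRK (15.6 CPM).

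**Figure D1:**
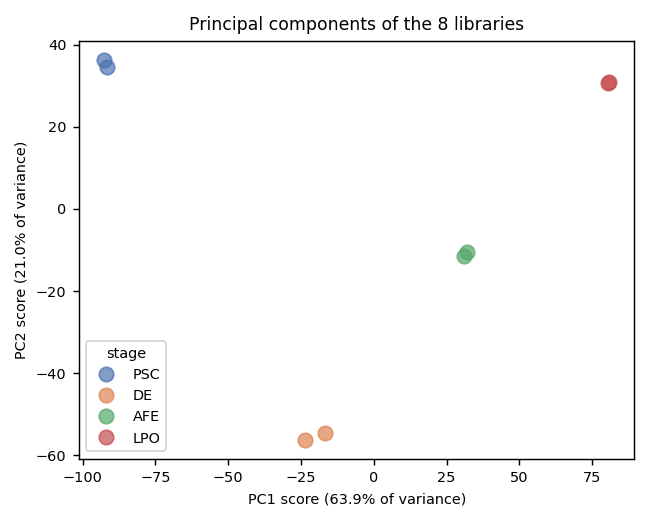
Principal components 1 and 2 of the 500 most variable genes (log2 CPM), with the share of variance in percent on each axis. Each point is a library, coloured by stage (PSC, DE, AFE, LPO; 2 libraries each), and the stages follow each other from left to right.

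**Figure D2:**
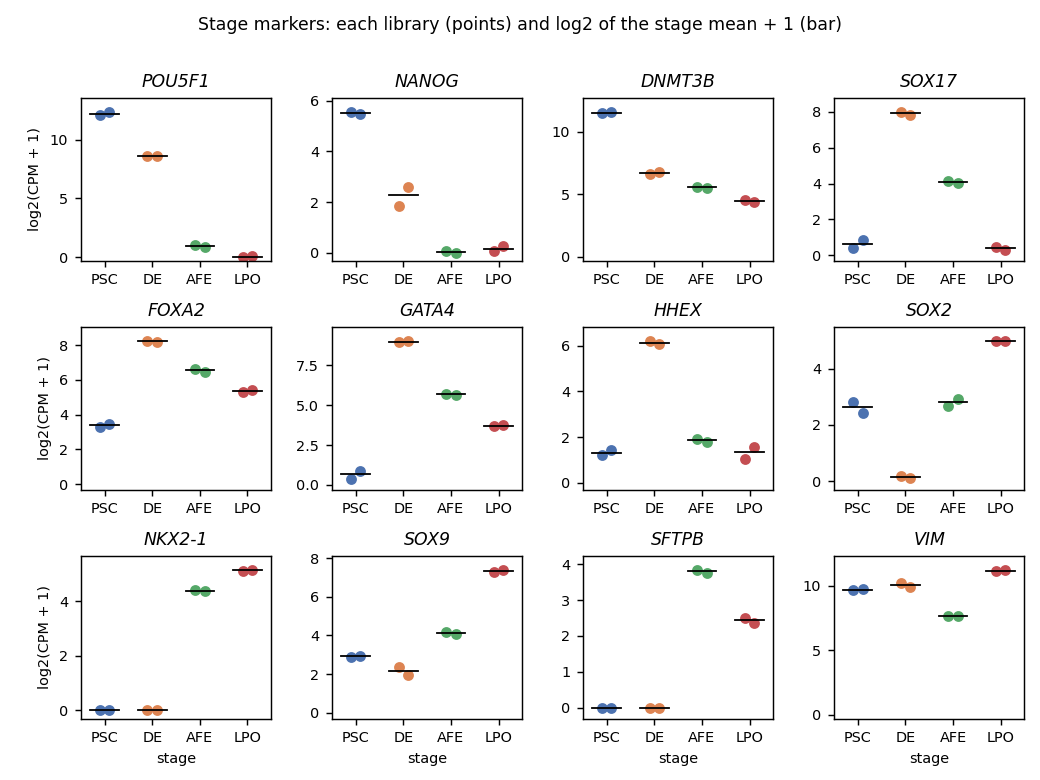
Levels of 12 genes (vertical axis, log2 of CPM + 1) by stage (horizontal axis: PSC, DE, AFE, LPO). Points are libraries and bars are stage means; POU5F1 is highest in PSC, SOX17 in DE, and NKX2-1 and SOX9 in LPO.

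The step from PSC to DE shows what changed as cells left pluripotency for endoderm. The regulators that hold pluripotency fell, and the transcription factors that specify endoderm rose. Basement membrane, simple-epithelial keratin and BMP-response genes rose with them, and so did genes of low oxygen. Genes named for mesenchyme, heart and blood vessel rose as well. None of these lists was called with an estimated correlation (adjusted p = 0.256 to 0.382), and the blood vessel call ended with quantile-normalized FPKM and with counts divided by 4 besides. Of 19346 genes, 10415 were called (5962 higher and 4453 lower in DE), 4407 and 2235 of them by 2-fold or more. The libraries of the stages did not overlap in 14055 genes, where random assignment gives 33.3%.

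POU5F1 (the core pluripotency regulator, chromosome 7, 23564659 to 23570600; the genome build is not given in the sources used here) fell from 4805 ± 497 to 387 ± 5.31 CPM (12.4-fold lower, log2 change -3.64 with SE 0.152, adjusted p = 1.1e-06). DNMT3B (the methyltransferase that sets DNA methylation anew, chromosome 17, 36345816 to 36386072) fell from 2927 ± 43.0 to 103 ± 6.36 CPM (28.4-fold lower, log2 change -4.83 with SE 0.0780, adjusted p = 2.9e-08). NANOG, a partner of POU5F1 in the pluripotency network, fell from 45.0 ± 1.36 to 3.85 ± 1.80 CPM (11.7-fold lower, adjusted p = 2.9e-04). SOX2, a factor shared by pluripotent and foregut cells, was low in PSC and fell from 5.26 ± 1.18 to 0.0956 ± 0.0360 CPM (ratio 55.1, 95% counting interval 17.0 to 253, lower, adjusted p = 4.4e-06). PRDM14 fell from 65.6 ± 1.18 to 0 CPM (at least 314-fold lower, adjusted p = 7.5e-06), and LEFTY2 from 2577 ± 165 to 1.77 ± 0.152 CPM (1457-fold lower, adjusted p = 4.5e-07). Also among the largest falls were TRIML2, a tripartite-motif protein (at least 108-fold lower, adjusted p = 1.6e-05), and CBLN1 (243-fold lower, adjusted p = 9.5e-07). Without DE replicate 2 the log2 change of NANOG was −4.14, against −3.55 with all libraries. Of 19 tested pluripotency genes 11 fell and 4 rose (camera adjusted p = 0.00786, adjusted p = 0.277 with an estimated correlation). The members that rose were LIN28A (blocks let-7 microRNA maturation), SALL4 (a zinc-finger factor), TFCP2L1 (a naive-state factor) and TERT (the catalytic subunit of telomerase).

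SOX17 (an endoderm-specifying factor, chromosome 4, 76854150 to 76857148) rose from 0.550 ± 0.357 to 239 ± 16.7 CPM (449-fold higher, log2 change 8.81 with SE 0.314, adjusted p = 6.8e-07). FOXA2 (a pioneer factor that opens endoderm chromatin, chromosome 17, 29997401 to 30001707) rose from 9.44 ± 1.14 to 294 ± 3.26 CPM (31.2-fold higher, log2 change 4.96 with SE 0.117, adjusted p = 1.3e-07). GATA4 (an endoderm and heart factor, chromosome 14, 14884662 to 14939941) rose from 0.565 ± 0.378 to 507 ± 16.0 CPM (928-fold higher, adjusted p = 1.9e-07). Its relative GATA6 rose from 0.992 ± 0.562 to 124 ± 5.11 CPM (122-fold higher, adjusted p = 8.2e-07). HHEX, a marker of anterior endoderm, rose from 1.48 ± 0.264 to 69.1 ± 5.00 CPM (47.0-fold higher, adjusted p = 3.9e-06). EOMES, which drives endoderm exit from the primitive streak, rose (1.94-fold higher, adjusted p = 0.00200), as did CXCR4, a chemokine receptor used to sort endoderm (2.05-fold higher, adjusted p = 0.00160). Of 15 definitive endoderm genes 11 rose and 4 fell (camera adjusted p = 0.00352, adjusted p = 0.277 with an estimated correlation). The 4 that fell were CER1 (a secreted NODAL and BMP inhibitor, 39.6-fold lower), KIT (a receptor of endoderm and germ cells), GSC (an organiser homeobox factor) and OTX2 (a head and anterior endoderm factor). The OTX2 call ended without PSC replicate 1 (log2 change −0.70), PSC replicate 2 (−0.61) or DE replicate 2 (−0.41). Without PSC replicate 1 and without PSC replicate 2, the log2 change was 8.22 and 9.64 for SOX17 and 9.25 and 10.73 for GATA4. That of GATA6 was 7.71 without PSC replicate 1 (6.93 with all libraries). Of 11 primitive streak genes 5 rose and 4 fell (camera adjusted p = 0.960). NODAL, the signal that induces endoderm, fell from 45.5 ± 8.61 to 1.77 ± 0.546 CPM (25.7-fold lower, adjusted p = 4.2e-04). It overlaps a gene with more counts on the opposite strand, and its values are uncertain.

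FN1 (fibronectin, chromosome 15, 117658156 to 117731014) rose from 31.7 ± 2.14 to 5955 ± 149.6 CPM (188-fold higher, log2 change 7.55 with SE 0.0718, adjusted p = 2.6e-09). With it rose the basement membrane chains COL18A1 (17.1-fold higher, adjusted p = 2.9e-08) and COL4A2 (18.6-fold higher, adjusted p = 3.6e-08) and the linker NID2 (37.4-fold higher, adjusted p = 1.3e-07). Of 20 matrix genes 18 rose and none fell (camera adjusted p = 5.9e-10, adjusted p = 0.256 with an estimated correlation). The keratins KRT19 (41.1-fold higher, adjusted p = 2.9e-08), KRT8 (15.4-fold higher, adjusted p = 2.9e-08) and KRT18 (8.83-fold higher, adjusted p = 1.1e-07) and the tight-junction claudin CLDN4 (11.8-fold higher, adjusted p = 3.3e-08) rose, KRT8 from 1846 ± 101 to 28519 ± 1181 CPM. Of 25 epithelial genes 17 rose and 4 fell (camera adjusted p = 0.00352, adjusted p = 0.348 with an estimated correlation). The 4 that fell were E-cadherin CDH1 (1.69-fold lower, adjusted p = 1.3e-05), the splicing regulator ESRP1, the polarity protein CRB3 and the transport protein MAL2.

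BMP-response genes rose as a group, 13 of 15 with none lower (camera adjusted p = 8.4e-07, adjusted p = 0.256 with an estimated correlation). They included the dominant-negative factors ID2 (168-fold higher, adjusted p = 3.6e-08) and ID3 (36.8-fold higher, adjusted p = 2.9e-08) and the inhibitory SMAD6 (187-fold higher, adjusted p = 8.8e-08). The ligand BMP4 itself rose from 1.06 ± 0.324 to 206 ± 57.8 CPM (191-fold higher, adjusted p = 7.5e-07). WNT targets rose, 12 of 16 (camera adjusted p = 0.00203, adjusted p = 0.277 with an estimated correlation), among them the feedback inhibitors NKD2 (21.2-fold higher, adjusted p = 1.3e-07) and APCDD1 (4.46-fold higher, adjusted p = 8.3e-06). The feedback scaffold AXIN2 fell. Of 21 hypoxia genes 17 rose (camera adjusted p = 2.3e-05, adjusted p = 0.382 with an estimated correlation), among them the angiogenic factor VEGFA (25.4-fold higher, adjusted p = 6.4e-08), the glucose transporter SLC2A1 (24.1-fold higher, adjusted p = 9.6e-08) and the peptide hormone ADM (247-fold higher, adjusted p = 9.6e-08). Carbonic anhydrase CA9 and the oxygen sensor EGLN3 fell.

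APOA1 (the main protein of high-density lipoprotein, chromosome 9, 44216392 to 44218713) rose from 29.9 ± 1.91 to 13303 ± 199.8 CPM (445-fold higher, log2 change 8.80 with SE 0.0830, adjusted p = 2.6e-09). HNF4A, a nuclear receptor of liver and visceral endoderm, rose from 0.342 ± 0.483 to 294 ± 21.3 CPM (929-fold higher, adjusted p = 5.4e-06). Without PSC replicate 1 the log2 change of HNF4A was 8.75 (9.86 with all libraries), and without PSC replicate 2 a fitted 17.16, with PSC at 0. Of 20 liver and pancreas genes 9 rose and 1 fell, the retinol carrier RBP4 (camera adjusted p = 0.0230, adjusted p = 0.300 with an estimated correlation). Albumin (ALB) and fibrinogen gamma (FGG), main products of liver, and PDX1, the pancreas factor, were among the 10 not called. The list's median log2 change was 4.60, or 2.48 with genes at 0 taken at their bound. The largest bounded rises outside the lists were HABP2 (a plasma protease), ALAS2 (the erythroid enzyme of haem synthesis) and NPPA. After them came IHH (a Hedgehog ligand of gut endoderm), from 0 to 44.7 ± 11.5 CPM (at least 137-fold higher, adjusted p = 2.0e-06).

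Of 28 mesenchyme genes 22 rose and none fell (camera adjusted p = 4.6e-05, adjusted p = 0.256 with an estimated correlation), among them N-cadherin CDH2 (7.71-fold higher, adjusted p = 1.5e-07) and the matrix protein POSTN (at least 4.36-fold higher, adjusted p = 1.6e-06). The POSTN call ended with quantile-normalized FPKM (log2 change 0.21). Of 14 heart and lateral mesoderm genes 10 rose (camera adjusted p = 8.0e-04, adjusted p = 0.277 with an estimated correlation), among them the cardiac myosin MYH6 (17.6-fold higher, adjusted p = 1.0e-06) and the factors GATA5 (25.9-fold higher, adjusted p = 1.2e-06) and MEF2C (45.0-fold higher, adjusted p = 5.1e-06). Cardiac actin ACTC1 fell. Of 15 endothelial and blood genes 11 rose (camera adjusted p = 0.0116, adjusted p = 0.294 with an estimated correlation), among them GATA2, a factor of blood and endothelium (47.8-fold higher, adjusted p = 6.8e-06), whose log2 change was 6.30 without PSC replicate 2. CD34, a surface protein of blood progenitors, fell, and so did PTPRC, the leukocyte phosphatase, from 0.476 ± 0.169 to 0 CPM (at least 2.28-fold lower, adjusted p = 0.0378). The CD34 call ended without PSC replicate 1 (log2 change −0.60), DE replicate 1 (−0.96), DE replicate 2 (−0.70) or any AFE or LPO library (−0.84 to −0.81). It also ended with no filter on low values (−0.81) and with only the 4 libraries compared (−0.84). The PTPRC call ended without any single PSC, DE, AFE or LPO library (fitted log2 change −8.22 to −7.45, with DE at 0), with no filter (fitted −7.81) and with the DESeq2 Wald test (fitted −7.37). Of 13 trophoblast and extraembryonic genes 7 rose (camera adjusted p = 0.00786, adjusted p = 0.256 with an estimated correlation), among them keratin KRT7 (2.67-fold higher, adjusted p = 1.1e-05). TFAP2C, a trophoblast and germ-cell factor, fell.

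The endothelial call ended with quantile-normalized FPKM (adjusted p = 0.164) and with counts divided by 4 (0.0512), and its adjusted p ran from 0.00578 to 0.294 over the alternatives. The other 11 called lists had an adjusted p of at most 0.0296 under the other alternatives run for lists (each scaling, the replicate block, counts divided by 4, each library left out). No list was called with an estimated correlation.

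The lists not called, with genes higher and lower of those tested, were anterior foregut (10 and 2 of 20, adjusted p = 0.267), lung progenitor (11 and 8 of 27, adjusted p = 0.202), mature airway and alveolus (8 and 2 of 22, adjusted p = 0.601), thyroid (1 and 3 of 8, adjusted p = 0.789) and hindgut (5 and 1 of 13, adjusted p = 0.539). Neural (1 and 5 of 17, adjusted p = 0.0551), NODAL and TGF-beta (5 and 4 of 12, adjusted p = 0.818), FGF and ERK (5 and 9 of 16, adjusted p = 0.0551), Hedgehog (3 and 2 of 10, adjusted p = 0.956), retinoic acid (8 and 4 of 16, adjusted p = 0.255) and Notch targets (4 and 1 of 11, adjusted p = 0.544) were not called either. The same held for anterior HOX (7 and 2 of 14, adjusted p = 0.275), posterior HOX (7 and 0 of 17, adjusted p = 0.0551), cell cycle (10 and 13 of 28, adjusted p = 0.139), stress (9 and 8 of 20, adjusted p = 0.818), p53 (8 and 5 of 14, adjusted p = 0.232), interferon (5 and 2 of 19, adjusted p = 0.789) and cholesterol genes (5 and 8 of 19, adjusted p = 0.139). Median, mean and test differed in sign for primitive streak (median −0.64, mean 1.25, test lower), NODAL and TGF-beta (0.30, −0.63, higher), Hedgehog (−0.17, 1.68, lower) and stress genes (0.16, −0.20, lower). Adjusted over the list alone, the counts higher and lower differed for primitive streak and mesendoderm (5 and 5), lung progenitor and bud tip (12 and 8), epithelial junction and keratin (17 and 5), mesenchyme (22 and 1), lateral mesoderm and cardiac (11 and 1), trophoblast and extraembryonic (8 and 1), NODAL and TGF-beta targets (6 and 4), cell cycle (11 and 14), hypoxia and glycolysis (18 and 2), stress and unfolded protein response (9 and 9) and cholesterol synthesis (5 and 10).

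The step from DE to AFE shows what changed between the stages named definitive endoderm and anterior foregut endoderm. The endoderm and BMP-response genes that marked DE fell, and NODAL-response genes fell too. Retinoic acid targets and anterior HOX genes rose steeply, foregut and pharyngeal factors rose, and NKX2-1, the factor that marks lung and thyroid primordia, appeared. Cholesterol synthesis genes fell together. The retinoic acid, anterior HOX and cholesterol calls held with an estimated correlation (each adjusted p = 0.0238). The endoderm, BMP, NODAL (each adjusted p = 0.0611) and foregut calls (adjusted p = 0.0901) ended. Of 19346 genes, 6838 were called (3467 higher and 3371 lower in AFE; 4535 without AFE replicate 2), 1792 and 1616 of them by 2-fold or more. The libraries of the stages did not overlap in 13341 genes, where random assignment gives 33.3%.

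NKX2-1 (chromosome 7, 63487807 to 63491575) rose from 0 to 19.8 ± 0.517 CPM (at least 95.0-fold higher, adjusted p = 8.8e-06). SFTPB (surfactant protein B, chromosome 3, 59101981 to 59112396) rose from 0 to 13.0 ± 0.574 CPM (at least 62.0-fold higher, adjusted p = 4.9e-05). The alveolar surfactant gene SFTPC was listed at 0 in both stages. SOX2, which marks foregut and future airway, rose from 0.0956 ± 0.0360 to 5.98 ± 0.883 CPM (ratio 62.6, 95% counting interval 19.3 to 279.8, higher, adjusted p = 1.2e-05). SOX9, a factor of the growing lung tips, rose from 3.47 ± 0.916 to 16.3 ± 0.838 CPM (4.71-fold higher, adjusted p = 4.6e-05). The Hedgehog ligand SHH rose from 0.367 ± 0.323 to 14.1 ± 0.0614 CPM (38.3-fold higher, adjusted p = 5.3e-04). The log2 change of SHH was 4.56 without DE replicate 1 and 6.64 without DE replicate 2. That of OSR1 was 11.23 without DE replicate 2 and a fitted 17.10 without DE replicate 1, with DE at 0. Of 27 lung progenitor genes 13 rose and 7 fell (camera adjusted p = 0.0986). The bud-tip factors ETV4 and ETV5 and the repressor ID2 (4.78-fold lower, adjusted p = 4.5e-06) were among those that fell. Of 20 foregut genes 11 rose and 3 fell (camera adjusted p = 0.00219, adjusted p = 0.0901 with an estimated correlation). Those that rose included PAX9, a pharyngeal pouch factor (12.4-fold higher, adjusted p = 4.7e-04). Those that fell were FOXA2 (3.20-fold lower, adjusted p = 1.6e-05), OTX2 and the heart and pharynx factor NKX2-5. OSR1 (a mesoderm and foregut zinc-finger factor, chromosome 3, 118757920 to 118765102) rose from 0.0605 ± 0.0856 to 298 ± 9.09 CPM (ratio 4917, 95% counting interval 1183 to 35296, higher, adjusted p = 5.8e-06).

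Retinoic acid targets rose in 15 of 16 genes (camera adjusted p = 6.0e-14, adjusted p = 0.0238 with an estimated correlation). They included the nuclear receptor NR2F2 from 0.766 ± 0.106 to 118 ± 5.64 CPM (154-fold higher, adjusted p = 2.0e-07) and the retinal reductase DHRS3 from 56.1 ± 3.60 to 469 ± 3.40 CPM (8.36-fold higher, adjusted p = 1.2e-06). Of 14 anterior HOX genes, which pattern the hindbrain and foregut level, 12 rose and none fell (camera adjusted p = 2.2e-12, adjusted p = 0.0238 with an estimated correlation). HOXB1 rose from 0 to 22.9 ± 1.82 CPM (at least 109.7-fold higher, adjusted p = 5.2e-05). HOXB2 rose from 1.36 ± 0.209 to 104 ± 24.8 CPM (76.4-fold higher, adjusted p = 7.3e-06) and HOXB3 from 0.462 ± 0.213 to 21.5 ± 3.15 CPM (46.4-fold higher, adjusted p = 2.0e-05). Posterior HOX genes (4 and 0 of 17, adjusted p = 0.0986) were not called as a group.

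**Figure D3:**
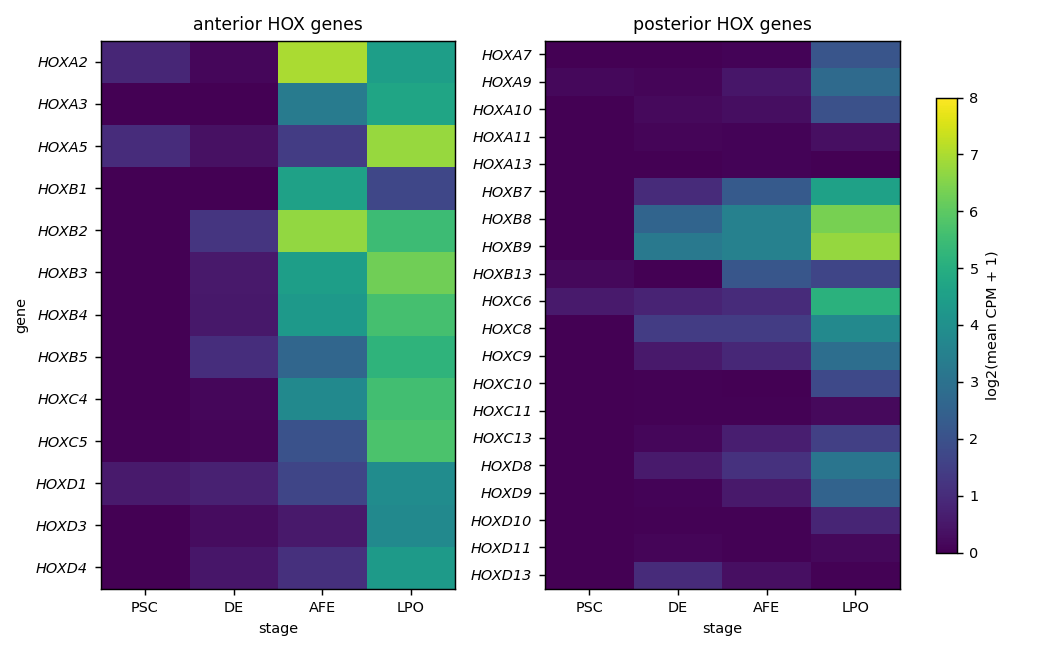
Mean level of HOX genes (colour, log2 of mean CPM + 1) by stage (columns: PSC, DE, AFE, LPO), with anterior genes and posterior genes in separate panels. Several anterior genes rose at AFE and others at LPO, and most posterior genes were highest at LPO.

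The DE markers fell. SOX17 fell from 239 ± 16.7 to 15.8 ± 1.06 CPM (15.2-fold lower, log2 change -3.92 with SE 0.223, adjusted p = 1.4e-05). GATA4 fell from 507 ± 16.0 to 50.3 ± 2.59 CPM (10.1-fold lower, adjusted p = 1.1e-05) and HHEX from 69.1 ± 5.00 to 2.60 ± 0.241 CPM (26.5-fold lower, adjusted p = 1.8e-05). EOMES fell from 60.8 ± 3.40 to 0 CPM (at least 307-fold lower, adjusted p = 5.9e-06). Of 15 definitive endoderm genes 12 fell (camera adjusted p = 2.0e-07, adjusted p = 0.0611 with an estimated correlation). FOXA1, the partner of FOXA2 in lung and gut, rose (3.23-fold higher, adjusted p = 3.8e-05). Of 11 primitive streak genes 7 fell (camera adjusted p = 4.4e-04, adjusted p = 0.217 with an estimated correlation), among them the growth factor FGF17 (20.7-fold lower, adjusted p = 5.6e-05). MIXL1, a streak homeobox factor, rose from 0.589 ± 0.635 to 7.34 ± 1.06 CPM (12.4-fold higher, adjusted p = 0.00760). Its log2 change was 5.69 without DE replicate 1 and 2.81 without DE replicate 2. POU5F1 fell further, from 387 ± 5.31 to 0.914 ± 0.161 CPM (422-fold lower, adjusted p = 4.8e-07). Of 19 pluripotency genes 9 fell and 2 rose, SOX2 and the nuclear receptor ESRRB (camera adjusted p = 0.0259, adjusted p = 0.219 with an estimated correlation). APOA1 fell from 13303 ± 199.8 to 264 ± 11.2 CPM (50.3-fold lower, adjusted p = 4.7e-08) and HNF4A from 294 ± 21.3 to 4.89 ± 0.999 CPM (60.0-fold lower, adjusted p = 4.5e-05).

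Of 15 BMP targets 11 fell and none rose (camera adjusted p = 2.8e-08, adjusted p = 0.0611 with an estimated correlation), among them SMAD6 (9.14-fold lower, adjusted p = 3.2e-06), the homeobox factor MSX2 (12.3-fold lower, adjusted p = 4.5e-06) and ID3 (3.16-fold lower, adjusted p = 4.6e-06). Of 12 NODAL and TGF-beta targets 9 fell (camera adjusted p = 1.1e-04, adjusted p = 0.0611 with an estimated correlation), among them the activin antagonist FST (74.7-fold lower, adjusted p = 4.5e-06). Of 14 heart and lateral mesoderm genes 8 fell (camera adjusted p = 0.0259, adjusted p = 0.288 with an estimated correlation), among them TBX20, a heart factor (66.8-fold lower, adjusted p = 5.6e-05). MYH6 (2.35-fold higher, adjusted p = 3.5e-04) and GATA5 rose. Of 19 cholesterol genes 15 fell and none rose (camera adjusted p = 1.5e-10, adjusted p = 0.0238 with an estimated correlation), among them IDI1, an isomerase of the isoprenoid steps (2.75-fold lower, adjusted p = 5.8e-06), and the sterol oxidase MSMO1 (2.97-fold lower, adjusted p = 6.5e-06). The kinase MVK was among the 4 not called.

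Of 28 cell cycle genes 16 fell (camera adjusted p = 0.0198, adjusted p = 0.144 with an estimated correlation), among them cyclin CCNB1 (1.88-fold lower, adjusted p = 5.4e-05) and the kinase CDK1 (1.97-fold lower, adjusted p = 3.1e-04). The 5 that rose were the replication genes PCNA, MCM2, MCM3, MCM7 and TYMS (2.09-fold higher, adjusted p = 2.9e-05). The KEGG pathway DNA replication, singled out after its values were seen, rose in 16 of 34 genes and fell in 1 (camera adjusted p = 0.0212, adjusted p = 0.533 with an estimated correlation). The MCM7 call ended without AFE replicate 1 (log2 change 0.37) or AFE replicate 2 (0.40). Of 21 hypoxia genes 13 fell (camera adjusted p = 5.3e-04, adjusted p = 0.444 with an estimated correlation), among them ADM (6.02-fold lower, adjusted p = 5.1e-06) and SLC2A1 (3.92-fold lower, adjusted p = 5.7e-06). The 4 that rose were EGLN3, CA9, NDRG1 (a stress-response protein) and ENO1 (glycolytic enolase). The CA9 call ended without DE replicate 1 (log2 change 0.48) or AFE replicate 2 (0.45). The NDRG1 and ENO1 calls ended without DE replicate 2 (0.70 and 0.34), AFE replicate 1 (1.14 and 0.58) or AFE replicate 2 (1.12 and 0.57), and that of ENO1 without LPO replicate 1 or 2 (0.57). ENO1 turned to −0.04 with quantile-normalized FPKM. Of 13 hindgut genes 4 rose and 3 fell (camera adjusted p = 0.976). CDX2, the intestinal homeobox factor, rose from 2.62 ± 0.604 to 23.8 ± 3.89 CPM (9.10-fold higher, adjusted p = 2.3e-04).

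The pluripotency call ended without PSC replicate 1 (adjusted p = 0.0556), PSC replicate 2 (0.0637), DE replicate 1 (0.0754) or AFE replicate 2 (0.0713) and ran from 0.00729 to 0.219 over the alternatives. The heart and lateral mesoderm call ended without AFE replicate 1 (0.0881; range 0.0123 to 0.288). The cell cycle call ended with counts divided by 4 (0.121; range 0.00900 to 0.144). With quantile-normalized FPKM the cell cycle and pluripotency calls ended (both 0.0560). The other 9 called lists had an adjusted p of at most 0.0123 under each scaling, the replicate block, counts divided by 4 and each library left out. With an estimated correlation the retinoic acid, anterior HOX and cholesterol calls held.

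Not called were mature airway and alveolus (5 and 5 of 22, adjusted p = 0.334), thyroid (0 and 1 of 8, adjusted p = 0.890), liver and pancreas (2 and 5 of 20, adjusted p = 0.372), epithelial (7 and 8 of 25, adjusted p = 0.554), mesenchyme (13 and 6 of 28, adjusted p = 0.155) and endothelial genes (0 and 4 of 15, adjusted p = 0.0861), given as genes higher and lower of those tested. Neither were neural (2 and 4 of 17, adjusted p = 0.487), trophoblast (3 and 3 of 13, adjusted p = 0.843), WNT (6 and 5 of 16, adjusted p = 0.976), FGF and ERK (3 and 8 of 16, adjusted p = 0.0986), Hedgehog (3 and 1 of 10, adjusted p = 0.155) and Notch genes (1 and 6 of 11, adjusted p = 0.109). Stress (3 and 10 of 20, adjusted p = 0.0505), p53 (8 and 4 of 14, adjusted p = 0.155), matrix (9 and 8 of 20, adjusted p = 0.976) and interferon genes (8 and 2 of 19, adjusted p = 0.0710) were also not called. Median, mean and test differed in sign for hindgut (median −0.36, mean −0.05, test higher), epithelial (−0.08, 0.06, lower), WNT (0.00, −0.90, higher) and matrix genes (0.06, 0.32, lower). Adjusted over the list alone, the counts higher and lower differed for definitive endoderm (1 and 13), lung progenitor and bud tip (15 and 9), mature alveolar and airway epithelium (7 and 5), liver and pancreas (3 and 5), epithelial junction and keratin (8 and 9), mesenchyme (14 and 7), trophoblast and extraembryonic (4 and 3), BMP targets (0 and 12), FGF and ERK targets (5 and 8), anterior HOX (13 and 0), cell cycle (5 and 17), hypoxia and glycolysis (4 and 15), p53 targets and apoptosis (9 and 4) and extracellular matrix and basement membrane (10 and 8).

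The step from AFE to LPO shows what changed between foregut cells and organoids. SOX9, SOX2 and NKX2-1 rose, but the lung progenitor list was not called, surfactant protein B fell and surfactant protein C stayed near the floor. Cell cycle genes fell almost without exception, and the keratins KRT8, KRT18 and KRT19 fell. Mesenchyme, FGF-response, hypoxia and posterior HOX genes rose. These 4 calls ended with an estimated correlation (adjusted p = 0.0681 to 0.548), and the cell cycle call held (adjusted p = 0.0425). Of 19346 genes, 11574 were called (5842 higher and 5732 lower in LPO), 4384 and 3985 of them by 2-fold or more. The libraries of the stages did not overlap in 16336 genes, where random assignment gives 33.3%. The median log2 change of all genes was 0.09 with TMM scaling and 0.41 with median centring, so changes of that size depend on the scaling.

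SOX9 (chromosome 12, 8642158 to 8647315) rose from 16.3 ± 0.838 to 159 ± 7.62 CPM (9.73-fold higher, log2 change 3.28 with SE 0.159, adjusted p = 1.3e-06). NKX2-1 rose from 19.8 ± 0.517 to 34.0 ± 0.377 CPM (1.71-fold higher, adjusted p = 0.00448) and SOX2 from 5.98 ± 0.883 to 30.5 ± 0.265 CPM (5.10-fold higher, adjusted p = 3.7e-05). ETV5, an FGF-driven factor of lung tips, rose from 7.06 ± 0.792 to 57.3 ± 4.63 CPM (8.11-fold higher, adjusted p = 5.4e-07), and MYCN, a growth factor-responsive MYC relative, fell from 139.6 ± 0.720 to 9.56 ± 0.654 CPM (14.6-fold lower, adjusted p = 5.6e-07). FOXA2 fell from 91.9 ± 6.86 to 40.6 ± 2.09 CPM (2.26-fold lower, adjusted p = 2.1e-05). Of 27 lung progenitor genes 11 rose and 7 fell (camera adjusted p = 0.284). SFTPB fell from 13.0 ± 0.574 to 4.40 ± 0.307 CPM (2.95-fold lower, adjusted p = 0.00355). SFTPC rose from 0 to 0.351 ± 0.126 CPM (at least 1.77-fold higher, adjusted p = 0.0287), a call that ended without AFE replicate 1, AFE replicate 2, LPO replicate 1 or LPO replicate 2 (fitted log2 change 6.86 to 7.60) and with no filter on low values (fitted 7.38). Not detectably changed was the secretoglobin SCGB3A2, an early airway marker, at 0.926 ± 0.295 CPM in LPO. The basal-cell factor TP63 rose from 1.02 ± 0.249 to 9.13 ± 0.0255 CPM (8.90-fold higher, adjusted p = 2.0e-04). Of 22 mature airway and alveolar genes 8 rose and 4 fell (camera adjusted p = 0.657).

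POSTN (periostin, a matrix protein of connective tissue, chromosome 11, 13224959 to 13258978) rose from 27.8 ± 0.571 to 2470.4 ± 16.0 CPM (88.9-fold higher, log2 change 6.47 with SE 0.0665, adjusted p = 1.1e-07). VIM (vimentin, the mesenchymal intermediate filament) rose from 201 ± 2.24 to 2279 ± 47.0 CPM (11.3-fold higher, adjusted p = 2.1e-07). CDH11 (a mesenchymal cadherin) rose from 5.55 ± 0.352 to 296 ± 13.7 CPM (53.2-fold higher, adjusted p = 1.6e-07) and PDGFRB from 11.1 ± 0.681 to 350.0 ± 12.3 CPM (31.6-fold higher, adjusted p = 4.6e-07). Of 28 mesenchyme genes 21 rose and 3 fell, smooth-muscle actin ACTA2, the actin-binding TAGLN and CDH2 (camera adjusted p = 2.6e-06, adjusted p = 0.0681 with an estimated correlation). TAGLN and CDH2 turned to 0.17 and 0.16 (log2) with FPKM, and their calls ended with the filter of 5 FPKM (−0.0526 and −0.0563) and with median centring (−0.00488 and −0.00845). The TAGLN call ended without AFE replicate 2 (−0.27), LPO replicate 1 (−0.33) or LPO replicate 2 (−0.36). The list's median log2 change was 3.46, or 3.50 with genes at 0 taken at their bound. Of 12 NODAL and TGF-beta targets 8 rose and 1 fell (camera adjusted p = 0.00994, adjusted p = 0.250 with an estimated correlation). The former included the matrix protein TGFBI from 40.8 ± 0.640 to 717 ± 2.81 CPM (17.6-fold higher, adjusted p = 1.5e-07) and SKIL, a SMAD repressor (10.4-fold higher, adjusted p = 4.9e-07).

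Of 25 epithelial genes 15 fell and 6 rose (camera adjusted p = 0.00994, adjusted p = 0.383 with an estimated correlation). The keratins KRT18 from 9347 ± 134 to 537 ± 30.4 CPM (17.4-fold lower, adjusted p = 1.4e-07) and KRT8 from 14394 ± 369.9 to 2097 ± 53.4 CPM (6.86-fold lower, adjusted p = 1.5e-07) fell. KRT19 (5.03-fold lower, adjusted p = 2.0e-07) and the adhesion molecule EPCAM (1.75-fold lower, adjusted p = 1.1e-04) fell as well, but with quantile-normalized FPKM the EPCAM call ended (log2 change −0.0144). Among those that rose were CDH1 (1.26-fold higher, adjusted p = 8.0e-04), KRT7 (1.69-fold higher, adjusted p = 2.0e-04), ESRP1, the junction protein OCLN and MAL2. Of the endoderm regulators, SOX17 (50.1-fold lower, adjusted p = 1.8e-06), GATA4 (4.14-fold lower, adjusted p = 2.1e-05) and GATA6 (1.96-fold lower, adjusted p = 0.00233) fell, the GATA6 call ending with FPKM at a pseudocount of 0.1 (log2 change −0.47). The intestinal factor CDX2 fell from 23.8 ± 3.89 to 0.745 ± 0.110 CPM (31.9-fold lower, adjusted p = 1.0e-05), while the intestinal cadherin CDH17 rose from 0.454 ± 0.112 to 40.1 ± 1.25 CPM (87.8-fold higher, adjusted p = 1.2e-06).

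Of 28 cell cycle genes 26 fell (camera adjusted p = 4.4e-11, adjusted p = 0.0425 with an estimated correlation). The spindle kinesin KIF11 rose, a call that ended without AFE replicate 1 (log2 change 0.48), AFE replicate 2 (0.47), LPO replicate 1 (0.43) or LPO replicate 2 (0.48). Among those that fell were BIRC5, the chromosome passenger survivin, from 177 ± 2.34 to 15.7 ± 0.710 CPM (11.3-fold lower, adjusted p = 1.5e-07) and CDC20, an activator of anaphase, from 289 ± 10.9 to 32.4 ± 0.898 CPM (8.93-fold lower, adjusted p = 1.5e-07). MCM2, a subunit of the replicative helicase, fell from 308 ± 10.3 to 36.9 ± 0.0730 CPM (8.36-fold lower, adjusted p = 1.5e-07), and so did TYMS, thymidylate synthase (7.71-fold lower, adjusted p = 1.8e-07). Of 16 FGF and ERK targets 13 rose (camera adjusted p = 0.00160, adjusted p = 0.170 with an estimated correlation), among them the phosphatase DUSP4 (6.26-fold higher, adjusted p = 7.6e-07) and the immediate-early factor EGR1 (22.2-fold higher, adjusted p = 4.2e-06). The phosphatase DUSP5 fell. Of 21 hypoxia genes 17 rose and 3 fell, CA9 and the glycolytic enzymes TPI1 and GAPDH (camera adjusted p = 0.00160, adjusted p = 0.548 with an estimated correlation). TPI1 turned to 0.52 (log2) with quantile-normalized FPKM and GAPDH to 0.16 with FPKM. The TPI1 call ended with FPKM (−0.10), and the GAPDH call with the filter of 5 FPKM (−0.0581), DESeq2 size factors (−0.27) and median centring (−0.0103). The GAPDH call ended without AFE replicate 1 or 2 (−0.33) or LPO replicate 1 (−0.34) or 2 (−0.35). VEGFA rose from 48.2 ± 1.36 to 557 ± 4.55 CPM (11.5-fold higher, adjusted p = 1.5e-07) and ADM (9.84-fold higher, adjusted p = 4.0e-07).

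Of 17 posterior HOX genes 11 rose and none fell (camera adjusted p = 0.00574, adjusted p = 0.373 with an estimated correlation), among them HOXB9 from 10.5 ± 1.17 to 106 ± 1.96 CPM (10.1-fold higher, adjusted p = 2.6e-06), HOXB8 (7.71-fold higher, adjusted p = 6.2e-05) and HOXC6 (35.0-fold higher, adjusted p = 4.3e-05). Anterior HOX genes were not called as a group (10 higher and 4 lower of 14, camera adjusted p = 0.116). HOXA5, a factor of lung mesenchyme, rose from 1.70 ± 0.0677 to 108 ± 8.35 CPM (63.3-fold higher, adjusted p = 6.4e-07). CYP26A1 (the enzyme that degrades retinoic acid, chromosome 14, 104563195 to 104567095) fell from 699.5 ± 7.52 to 11.1 ± 0.298 CPM (63.0-fold lower, adjusted p = 7.1e-07). Of 16 retinoic acid targets 5 rose and 9 fell (camera adjusted p = 0.156).

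KEGG pathways of 10 to 300 tested genes (318) were tested for enrichment and singled out after their values were seen. The Ribosome pathway fell in 121 of 125 genes and rose in none (camera adjusted p = 2.4e-32, and adjusted p = 0.115 with an estimated correlation). Oxidative phosphorylation fell in 90 of 111 genes and rose in 5 (1.1e-18, and 0.102 with an estimated correlation). DNA replication fell in 32 of 34 genes and Proteasome in 35 of 41. The DNA replication genes had fallen in 22 of 34 in DE against PSC and risen in 16 in AFE against DE. In DE against PSC the Ribosome genes had fallen in 94 of 125, and in AFE against DE they had risen in 92. KEGG pathways called numbered 87 in DE against PSC, 20 in AFE against DE, 154 in LPO against AFE and 178 in LPO against PSC, and 0 with an estimated correlation.

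The epithelial and NODAL calls ended with quantile-normalized FPKM (adjusted p = 0.348 and 0.106) and ran from 8.9e-04 to 0.383 and from 0.00895 to 0.250 over the alternatives. The other 5 called lists had an adjusted p of at most 0.0170 under each scaling, the replicate block, counts divided by 4 and each library left out. With an estimated correlation the cell cycle call alone held.

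Not called, with genes higher and lower of those tested, were pluripotency (3 and 5 of 19, adjusted p = 0.663), primitive streak (1 and 1 of 11, adjusted p = 0.900), definitive endoderm (2 and 9 of 15, adjusted p = 0.102), foregut (6 and 7 of 20, adjusted p = 0.848), thyroid (0 and 2 of 8, adjusted p = 0.848), liver and pancreas (2 and 7 of 20, adjusted p = 0.310) and hindgut genes (5 and 3 of 13, adjusted p = 0.848). The same held for heart and lateral mesoderm (5 and 3 of 14, adjusted p = 0.848), endothelial (5 and 2 of 15, adjusted p = 0.531), neural (8 and 0 of 17, adjusted p = 0.0669), trophoblast (3 and 3 of 13, adjusted p = 0.848), WNT (8 and 3 of 16, adjusted p = 0.201), BMP (5 and 4 of 15, adjusted p = 0.881), Hedgehog (7 and 1 of 10, adjusted p = 0.116) and Notch genes (5 and 2 of 11, adjusted p = 0.267). Stress (14 and 5 of 20, adjusted p = 0.0806), p53 (9 and 3 of 14, adjusted p = 0.171), matrix (9 and 7 of 20, adjusted p = 0.657), interferon (9 and 1 of 19, adjusted p = 0.102) and cholesterol genes (11 and 7 of 19, adjusted p = 0.138) were not called either. Median, mean and test differed in sign for thyroid (median 0.39, mean 0.03, test lower) and BMP genes (−0.02, 0.33, higher). Adjusted over the list alone, the counts higher and lower differed for primitive streak and mesendoderm (0 and 1), thyroid (0 and 1), hindgut and intestine (6 and 3), mesenchyme (22 and 3), retinoic acid targets (5 and 10) and posterior HOX (12 and 0).

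**Figure D4:**
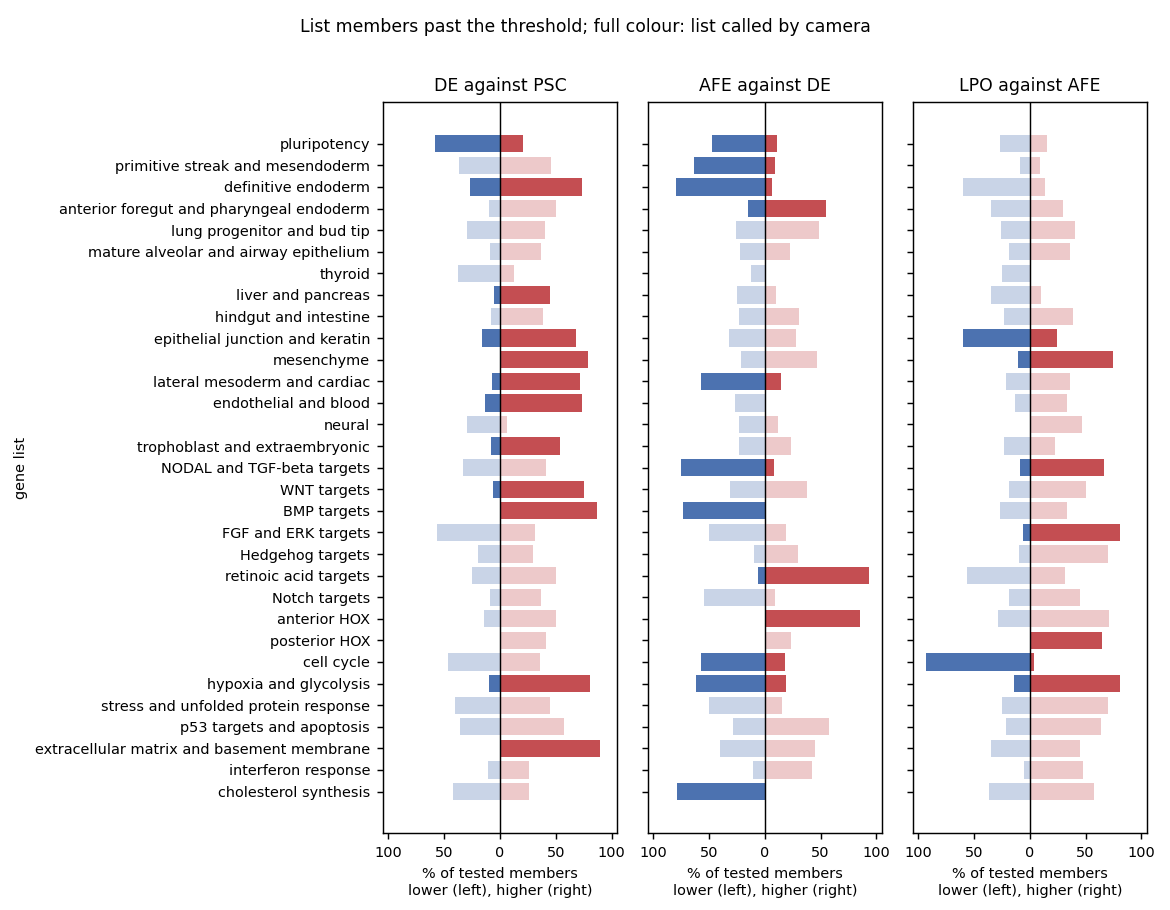
Percent of each list's tested genes called lower (left) and higher (right) in each step (DE against PSC, AFE against DE, LPO against AFE) for 31 gene lists. Full colour marks lists called by camera with the preset correlation.

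LPO against PSC gives the net change from the start to the end of the protocol. Pluripotency and cell cycle genes were lower in the organoids, and lung progenitor, foregut, HOX and mesenchyme genes were higher. With an estimated correlation the cell cycle call held (adjusted p = 0.0330) and the others ended (adjusted p = 0.0791 to 0.150). Of 19346 genes, 13602 were called (8031 higher and 5571 lower in LPO), 6663 and 4261 of them by 2-fold or more. The libraries did not overlap in 16680 genes, where random assignment gives 33.3%. The median log2 change of all genes was 0.49 with TMM scaling, 0.37 with DESeq2 size factors and 0.58 with median centring.

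POU5F1 fell from 4805 ± 497 to 0.0252 ± 0.0356 CPM (ratio 190851, 95% counting interval 34189 to 7524129, lower, adjusted p = 3.3e-08), and DNMT3B from 2927 ± 43.0 to 21.2 ± 1.44 CPM (138-fold lower, adjusted p = 1.2e-08). VRTN, a vertebra-number gene of pigs, fell from 269 ± 29.4 to 0 CPM (at least 1789.7-fold lower, adjusted p = 3.4e-07), and OTX2 from 169 ± 7.82 to 0 CPM (at least 1126-fold lower, adjusted p = 3.1e-07). SOX2 rose from 5.26 ± 1.18 to 30.5 ± 0.265 CPM (5.78-fold higher, adjusted p = 2.0e-05). Of 19 pluripotency genes 13 fell (camera adjusted p = 0.00327, adjusted p = 0.110 with an estimated correlation). SOX2, the barrier-epithelium factor KLF4, SALL4 and TFCP2L1 rose. Without LPO replicate 1 the log2 change of POU5F1 was −16.53 (−17.43 with all libraries), and without LPO replicate 2 a fitted −21.06, with LPO at 0. Of 28 cell cycle genes 26 fell and KIF11 rose (camera adjusted p = 9.4e-14, adjusted p = 0.0330 with an estimated correlation).

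Lung progenitor genes rose, 20 of 27 (camera adjusted p = 0.00111, adjusted p = 0.110 with an estimated correlation). In contrast ETV4, ETV5, the FGF receptor FGFR2, the epithelial factor GRHL2, MYCN and the calcium-binding TESC fell. The GRHL2 call ended with FPKM at pseudocounts 1, 0.1 and 0.5 (log2 change −0.18, −0.21 and −0.19). NKX2-1 rose from 0 to 34.0 ± 0.377 CPM (at least 104-fold higher, adjusted p = 8.0e-07) and SOX9 from 6.52 ± 0.0266 to 159 ± 7.62 CPM (24.4-fold higher, adjusted p = 2.2e-07). The epithelial factor ELF3 rose from 2.00 ± 0.867 to 825 ± 20.7 CPM (419-fold higher, adjusted p = 6.1e-08). FOXP4, a lung forkhead repressor, rose from 25.8 ± 0.335 to 363 ± 8.90 CPM (14.1-fold higher, adjusted p = 1.1e-07). SFTPB rose from 0 to 4.40 ± 0.307 CPM (at least 13.4-fold higher, adjusted p = 2.3e-05). MMP7, an epithelial metalloprotease, rose from 0 to 288 ± 0.407 CPM (at least 881-fold higher, adjusted p = 7.6e-07), and the laminin chain LAMB3 from 0 to 158 ± 2.63 CPM (at least 483-fold higher, adjusted p = 8.6e-07). Foregut genes rose in 14 of 20 (camera adjusted p = 0.00594, adjusted p = 0.110 with an estimated correlation), OTX2 falling. GBX2, a hindbrain-border factor, was called lower, but lay below the floor in both stages.

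Mesenchyme genes rose in 27 of 28 (camera adjusted p = 7.0e-10, adjusted p = 0.0867 with an estimated correlation), TWIST2, a connective-tissue factor, falling. POSTN rose from 0 to 2470.4 ± 16.0 CPM (at least 7553-fold higher, adjusted p = 1.1e-08) and CDH11 from 5.85 ± 0.116 to 296 ± 13.7 CPM (50.6-fold higher, adjusted p = 4.5e-08). COL6A3 (a collagen of connective tissue) rose from 0 to 275 ± 9.24 CPM (at least 842-fold higher, adjusted p = 1.0e-07). Matrix genes rose in 19 of 20 (camera adjusted p = 3.3e-09, adjusted p = 0.110 with an estimated correlation), the laminin chain LAMA1 falling. Anterior HOX genes rose in 14 of 14 (camera adjusted p = 6.2e-08, adjusted p = 0.0791 with an estimated correlation). Posterior HOX genes rose in 16 of 17 (camera adjusted p = 0.00115, adjusted p = 0.150 with an estimated correlation). HOXB6, which is in neither list, rose from 0 to 203 ± 9.52 CPM (at least 620.3-fold higher, adjusted p = 4.7e-08). The median log2 change of mesenchyme genes was 8.12 (5.61 with genes at 0 at their bound), of anterior HOX genes 13.34 (6.55) and of posterior HOX genes 10.46 (4.31).

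Retinoic acid targets rose in 13 of 16 (camera adjusted p = 4.5e-05, adjusted p = 0.110 with an estimated correlation), CYP26C1 among those falling. BMP targets rose in 13 of 15 (camera adjusted p = 2.1e-04, adjusted p = 0.110 with an estimated correlation), the iron hormone HAMP falling. WNT targets rose in 12 of 16 (camera adjusted p = 8.5e-04, adjusted p = 0.113 with an estimated correlation). SP8, a limb-bud factor, fell from 0.369 CPM in PSC, near the floor of 3 read pairs, to 0 in LPO (at least 2.46-fold lower). Hypoxia genes rose in 18 of 21 (camera adjusted p = 2.0e-05, adjusted p = 0.379 with an estimated correlation), CA9 and TPI1 falling. Interferon-response genes rose in 14 of 19 (camera adjusted p = 0.0105, adjusted p = 0.110 with an estimated correlation). The antiviral OAS2 and the RNA sensor DDX58 fell. Trophoblast genes rose in 11 of 13 (camera adjusted p = 0.0101, adjusted p = 0.110 with an estimated correlation). Heart and lateral mesoderm genes rose in 10 of 14 (camera adjusted p = 0.0260, adjusted p = 0.337 with an estimated correlation), ACTC1 falling (31.2-fold lower, adjusted p = 3.8e-05). Of 14 p53 targets 11 rose (camera adjusted p = 0.0281, adjusted p = 0.197 with an estimated correlation), among them the cycle inhibitor CDKN1A from 12.2 ± 0.0964 to 192 ± 1.72 CPM (15.8-fold higher, adjusted p = 4.8e-08). BAX, PMAIP1 and AEN, which promote cell death, fell.

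Among the falls and rises against their list, single libraries ended the calls of TWIST2 (fitted log2 change −5.45 without PSC replicate 1, −4.93 without LPO replicate 1), LAMA1 (−0.23 without PSC replicate 2, −0.29 without LPO replicate 1), DDX58 (−1.68 without PSC replicate 2, −1.46 without LPO replicate 1) and OAS2 (−0.64 without LPO replicate 1). The HAMP call ended without any PSC or LPO library or DE replicate 2 (−2.13 to −1.44), with no filter on low values (−1.68) and with median centring (−1.60). The SALL4 call ended without any library but PSC replicate 1 (0.49 to 0.98) and with only the 4 libraries compared (0.84). GBX2 stood at 0.109 CPM in PSC and 0 in LPO, both below the floor of 3 read pairs, so no fold can be bounded for it. Its call ended without any PSC, AFE or LPO library (fitted log2 change −5.89 to −5.65) and with counts divided by 4 (fitted −3.79). The LAMA1 call ended with the filter of 5 FPKM (−0.0987) and with median centring (−0.21), the OAS2 and TPI1 calls with FPKM (−0.27 and −0.14), and the KIF11 and AEN calls with quantile-normalized FPKM (0.26 and −0.14). LAMA1 turned to 0.09 with FPKM, and SALL4 to −0.18 and TPI1 to 0.55 with quantile-normalized FPKM.

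The p53 call ended without PSC replicate 1 (adjusted p = 0.0786), AFE replicate 1 (0.0668), AFE replicate 2 (0.0683) or LPO replicate 2 (0.0535) and ran from 0.0223 to 0.197 over the alternatives. With counts divided by 4 the heart (0.128; range 0.0164 to 0.337) and trophoblast calls (0.0617; range 0.00643 to 0.152) ended, and with quantile-normalized FPKM as well (0.248 and 0.152). The other 13 called lists had an adjusted p of at most 0.0202 under each scaling, the replicate block, counts divided by 4 and each library left out. With an estimated correlation the cell cycle call alone held.

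Not called, with genes higher and lower of those tested, were primitive streak (3 and 7 of 11, adjusted p = 0.0575), definitive endoderm (6 and 5 of 15, adjusted p = 0.949), mature airway and alveolus (15 and 2 of 22, adjusted p = 0.115), thyroid (1 and 1 of 8, adjusted p = 0.757), liver and pancreas (10 and 1 of 20, adjusted p = 0.417), hindgut (5 and 2 of 13, adjusted p = 0.563) and epithelial genes (12 and 8 of 25, adjusted p = 0.753). The same held for endothelial (10 and 0 of 15, adjusted p = 0.0960), neural (6 and 5 of 17, adjusted p = 0.757), NODAL and TGF-beta (6 and 5 of 12, adjusted p = 0.952), FGF and ERK (8 and 3 of 16, adjusted p = 0.753), Hedgehog (7 and 1 of 10, adjusted p = 0.231), Notch (5 and 4 of 11, adjusted p = 0.553), stress (10 and 8 of 20, adjusted p = 0.879) and cholesterol genes (7 and 9 of 19, adjusted p = 0.297). Median, mean and test differed in sign for definitive endoderm (median 0.07, mean −1.31, test higher), NODAL and TGF-beta (0.81, −1.30, lower), neural (0.19, 0.85, lower), Notch (1.06, −0.01, higher) and thyroid genes (−0.09, 1.08, lower). Adjusted over the list alone, the counts higher and lower differed for thyroid (0 and 1), liver and pancreas (6 and 1) and hindgut and intestine (3 and 2).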

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

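The tests with quantile-normalized FPKM and with counts divided by 4 were chosen only after the data were seen, and all other alternatives before. Called genes numbered 10415 (DE against PSC), 6838 (AFE against DE), 11574 (LPO against AFE) and 13602 (LPO against PSC). With a library left out they ran from 9052 to 10054, 4535 to 7894, 9315 to 12107 and 11374 to 13443, the lowest in AFE against DE being without AFE replicate 2. The stage left with a lone library is assumed to vary like the others. Under the other alternatives they ran from 7520 to 11007, 5264 to 7826, 8155 to 13178 and 8604 to 13840.

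Genes that differ among the stages (15323) ran from 13378 to 15021 with a library left out, those highest in PSC from 3805 to 4047, in DE from 2344 to 2613, in AFE from 2396 to 2699 and in LPO from 4727 to 5904. The filter of 5 FPKM tests fewer genes (9676) and called 8604 in LPO against PSC and 9491 among the stages, with 1402 highest in DE, 1630 in AFE and 3628 in LPO. With limma on FPKM, 1751, 1748 and 1734 genes were highest in AFE (pseudocounts 1, 0.5 and 0.1), and the cause was not tested.

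The share of called genes that were higher moved from 57.2% to 43.1% in DE against PSC and from 59.0% to 49.7% in LPO against PSC with quantile-normalized FPKM, and from 50.5% to 62.9% in LPO against AFE with FPKM. The median of all genes moved from 0.08 to 0 in DE against PSC with DESeq2 size factors or median centring and from 0.09 to 0.41 in LPO against AFE with median centring.

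Lists called with a library left out numbered 12 to 15, 11 to 14, 7 to 8 and 15 to 16. An estimated correlation left 0, 3, 1 and 1 of 12, 12, 7 and 16. With the replicate number as a block the calls were 9759, 6137, 10788 and 12596 genes, and the pluripotency (adjusted p = 0.0686; range 0.00729 to 0.219) and heart and lateral mesoderm calls (0.0505; range 0.0123 to 0.288) in AFE against DE and the p53 call in LPO against PSC (0.0686; range 0.0223 to 0.197) ended. So did the calls of CD34 (log2 change −0.81) and PTPRC (fitted −7.98) in DE against PSC, SFTPC (fitted 7.35) in LPO against AFE and HAMP (−1.72) in LPO against PSC, and no other list or named gene lost its call under the block. Nothing shows that equal numbers pair libraries: differences between replicates correlated across 7470 genes at −0.0171 to 0.0328 between stages.

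Of the called genes named, 62 of 66, 48 of 52, 43 of 51 and 30 of 41 kept direction and call under every alternative that gave a value. In LPO against AFE, with FPKM at pseudocounts 1, 0.1 and 0.5 and with quantile-normalized FPKM, TAGLN reversed to 0.17, 0.17, 0.17 and 0.55, CDH2 to 0.16, 0.16, 0.16 and 0.0323, and GAPDH to 0.16, 0.16, 0.16 and 0.82 (log2). TPI1 reversed to 0.52 with quantile-normalized FPKM, and to 0.55 in LPO against PSC. There LAMA1 reversed to 0.0858, 0.10 and 0.0946 with FPKM at pseudocounts 1, 0.1 and 0.5, and SALL4 to −0.18 with quantile-normalized FPKM. In AFE against DE, ENO1 reversed to −0.0397 with quantile-normalized FPKM. Without reversing, calls ended in LPO against PSC for GRHL2 and OAS2 with FPKM (−0.18 and −0.27 at pseudocount 1) and for KIF11 (0.26) and AEN (−0.14) with quantile-normalized FPKM. The cause was not tested.

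Depth limits genes near the floor: at 0.150 to 0.357 CPM a gene rests on 3 read pairs in a library.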

Other observations

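The tests of hepatocyte-like cells and of the level of smooth muscle genes were chosen only after their results were seen, and so were the KEGG tests. The other tests below were chosen before their own results, but after the patterns they address were seen.

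Several values stand apart from the stage names. SOX2 stood at 5.26 CPM in PSC, below its 30.5 CPM in LPO. MIXL1, a primitive streak gene, reached 7.34 CPM in AFE, and CDX2, an intestinal gene, 23.8 CPM there. SFTPB was highest in AFE at 13.0 CPM against 4.40 CPM in LPO. In LPO the macrophage elastase MMP12 stood at 9.33 CPM, the tendon gene TNMD at 10.3 CPM and the goblet-cell gene CLCA1 at 9.72 CPM.

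Ribosomal protein genes were lower in LPO than in AFE, with a median log2 change of −1.93. After the trend over transcript length was subtracted the median was −1.23 (quartiles −1.85 and −0.87), which argues against length bias as the whole cause. Of 10000 random lists matched on expression, 0% had a median as low as −1.93, the lowest being −1.25 and the middle −0.72. This argues against abundance of the genes as the whole cause. The random lists hold unrelated genes, whose medians vary less than those of genes that move together. With quantile-normalized FPKM the median of the ribosomal protein genes was −0.96, so scaling may account for part of its size. Length, abundance and scaling were weighed separately, and their joint effect was not tested. Whether the change of stage itself lowers these genes stays open and was not tested.

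Mesenchyme genes were higher in LPO than in AFE, and fibroblast-type or smooth muscle cells in the organoid cultures are candidate sources. The median level of 10 smooth muscle genes (the 8 of the added list, ACTA2 and TAGLN) in LPO was 0.311% of that of POSTN. ACTA2 stood at 7.57 CPM (41.5 CPM in AFE), MYH11 at 1.87 CPM and MYOCD at 0. TAGLN, DES and MYLK stood at 1% of POSTN or more. The comparison with POSTN, a single abundant gene, was chosen after its result was seen. It therefore cannot decide whether smooth muscle cells were the main source of the abundant matrix genes. Of 7 tested genes of the smooth muscle list 4 rose (57.1%), with DES at 61.1 CPM, and CNN1 and LMOD1 fell. That share lies between the 50% and 80% set beforehand, so smooth muscle cells stay open as a source. Of 15 tested fibroblast genes 11 rose (73.3%), with BGN at 359.6 and MMP2 at 420.2 CPM in LPO (80.2 and 223 CPM in AFE). PCOLCE, MFAP5 and FBLN1 fell. The share lies between the 50% and 80% set beforehand, so fibroblast-type cells stay open. They cannot be told apart from epithelial cells that took on such genes. In AFE 11 of 15 fibroblast genes and 6 of 8 genes of the smooth muscle list already stood above 1 CPM, and 0 of them are in the fixed lists.

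APOA1 and HNF4A were high in DE. Hepatocyte-like cells would bring TTR, ALB, APOB and RBP4. The highest of these, RBP4 at 2.48 CPM, came to 0.0187% of APOA1. This argues against such cells as the source, but the test was chosen after its result was seen. Of 20 tested liver and pancreas genes, however, 9 rose in DE, with TBX3 at 78.6 and APOC3 at 15.2 CPM, 1 fell and 10 were not called. Primitive endoderm-type cells, an extraembryonic lineage that also makes apolipoproteins, are a candidate source. Of 11 tested genes of such a list 10 rose from PSC to DE (90.9%), with PTH1R at 127 CPM, DAB2 at 86.1 CPM and BMP2 at 55.9 CPM. SOX7 reached only 1.68 CPM in DE, and CUBN stood at 0. LRP2 and CITED1 were highest in AFE (50.0 and 3.81 CPM) and THBD and PLOD2 in LPO (16.7 and 328 CPM). Matrix genes (18 of 20) and BMP targets (13 of 15) rose in DE as well, so such a share cannot single out this lineage. The apolipoprotein APOB stood at 0.227 CPM in DE, and this low level does not favour this lineage over hepatocyte-like cells. The low TTR, ALB and RBP4 were not weighed against this lineage. Of the 11 members in the file, 4 stood above 1 CPM in PSC already and 0 are in the fixed lists. Definitive endoderm that expresses these genes itself stays open and was not tested.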
